A study of Mus musculus with 2 samples.

How the data were processed

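The data are tag counts per gene from 2 SOLiD SAGE libraries of mouse lung fibroblasts, 1 from mice given saline and 1 from mice given bleomycin, each from 3 mice at day 14. Per the labels' protocols, lungs were digested with collagenase, dispase and deoxyribonuclease, reporter-positive cells without lineage markers were sorted, and total RNA went into 3′ tag libraries. Which lineage markers were used is not given in the sources used here. The submitters' processing notes name BWA 0.6.2 and mm9, with no role for either. How tags were assigned to transcripts, and whether strand was used, is not given in the sources used here, so genes that overlap, have antisense partners or share tags with a close copy, such as ribosomal protein, haemoglobin, histocompatibility, heat shock, glutathione transferase and serum amyloid genes, are uncertain.

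The deposited table gives a whole-number count for each gene and library. The values were checked for signs of scaling: the totals of 1080798 and 1099840 differ, every whole number below 218 in the saline and below 203 in the bleomycin library occurs, and the variance of low genes between the libraries was 2.60 times the binomial variance at sums of 10 to 19 counts. That variance was taken between a saline and a bleomycin library, so real differences also raise it and it cannot tell scaled from raw counts. No label says whether counts were scaled before deposit, and the similar totals leave this open, so tests and intervals hold only if the values are raw counts. No molecular identifiers are named in the labels, so intervals and floors cover counting error only.

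The deposited table held 16040 genes after 1 blank line was left out. Symbols turned into dates by spreadsheet software were recovered for 21 genes from their descriptions. A further 33 entries carried a phrase other than the gene symbol; they hold 0.86% of all counts, may pool several genes, and were kept in totals and tests but matched to no gene name. No symbol occurred more than once, and 2163 genes were at 0 in both libraries. Older and current symbols were matched through transcript records in a RefSeq gene table of assembly GRCm38, which covered 14449 genes (90.1%). Because that assembly differs from mm9, no coordinates are given.

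Library sizes were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 1.01 for saline and 0.986 for bleomycin. The quasi-likelihood test of edgeR needs replicates and could not be fitted with 1 library per group. Each gene with at least 10 counts over both libraries was tested with a two-sided exact binomial test of its bleomycin count given its sum, and p-values were adjusted by the Benjamini-Hochberg method over the 9369 genes tested. A call needed an adjusted p under 0.05 and a ratio of at least 2 in either direction. Log2 ratios have 0.5 added to each count, and ratios have exact Clopper-Pearson 95% intervals. A gene at 0 in a library was given a bound from a floor of 3 counts in that library. This bound takes the other count as given, so the exact interval, which covers the error of both counts, reaches lower, and its limit is printed beside the bound. A single count is worth 0.912 CPM in the saline and 0.922 CPM in the bleomycin library, and tested genes had a median of 26 and 25 counts. Across tested genes, which are not independent replicates, log2(CPM + 1) of the libraries had a Pearson correlation of 0.85 and a Spearman correlation of 0.833. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

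Before the data were examined, 40 gene lists were fixed, 26 of pathways and fibroblast genes and 14 of markers of other cell types, with 1097 members of which 1025 matched a gene in the table. For each list with at least 3 tested members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of abundance, as a description of these libraries. A list stood apart when its median lay within the lowest or highest 2.5% of them. The rule for named genes, fixed at the same time, took 8 identity checks, the 12 largest and 12 smallest ratios among called genes with at least 50 counts in the higher library and a symbol that is not a clone or model name, up to 4 called members of each list (2 per direction first), and the most abundant member of a list with no call. A few genes that this rule takes are not reported here. Any other gene is said to be chosen after its values were seen.

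The test was tried on simulated data for bleomycin against saline, drawn from the observed means and library sizes, with 200 changed genes among 9340 tested. It recovered 4.0% of genes changed 1.5-fold, 42.0% at 2.5-fold, 66.0% at 4-fold and 96.0% at 8-fold, with 50 genes at each size, and called 1 unchanged gene. Because a call needs a ratio of at least 2, the low recovery at 1.5-fold follows in part from that rule. The interval held a ratio of 1 for 96.3% of unchanged genes. Alternatives were DESeq2 1.42.0 size factors, total counts, totals without the 20 most abundant genes, no minimum and a minimum of 50 counts, ratios of at least 1.5 and 3, Bonferroni adjustment, Fisher's exact test, thinning the deeper library to the depth of the other, a prior count of 5 and, added after seeing the data, leaving out predicted transcripts.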

Results

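Lung fibroblasts of mice were profiled 14 days after an intratracheal dose of saline or of bleomycin, a DNA-damaging drug widely used to produce lung fibrosis in rodents. The mice carried an enhanced green fluorescent protein reporter driven by Col1a2, a type 1 collagen gene. Dissociated lung cells that lacked lineage markers and carried the reporter were sorted, and their RNA was measured by serial analysis of gene expression (SAGE), which counts short tags near the 3′ end of transcripts. The labels give 1 library for saline and 1 for bleomycin, each from fibroblasts of 3 mice. The saline library held 1080798 counts over 12275 genes and the bleomycin library 1099840 counts over 12918 genes. The most abundant gene in both was Mgp, which encodes an inhibitor of calcification in the matrix, with 4.06% of saline counts and 6.20% of bleomycin counts. A count of 0 allows a level of up to 2.74 CPM, the count scaled to library size, in the saline library and 2.77 CPM in the bleomycin library.

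The comparison of bleomycin with saline asks how expression in lung fibroblasts differs during bleomycin-induced fibrosis. In the bleomycin library, the median ratios of collagen, lung fibrosis-associated fibroblast and cell cycle genes lay above those of random gene lists, and the medians of alveolar and adventitial fibroblast genes lay below them. Medians of endothelial (−3.07), alveolar type 2 (−1.82) and airway markers (−1.79) and of immediate early and dissociation-induced genes (−0.65) also lay below random lists. So did those of smooth muscle (−0.99) and pericyte markers (−0.65) and of interferon-induced and antigen presentation (−0.78) and lipid metabolism genes (−0.31). The alveolar type 2 and airway medians rest on 4 and 3 tested genes, and the airway median is the ratio of Tppp3 alone. The airway, smooth muscle, pericyte and lipid metabolism medians left the lowest 2.5% under some alternatives. The median of oxidative phosphorylation genes (0.30) lay above random lists. Col1a2, the gene whose promoter drove the reporter, was 3.47-fold higher (3.28 to 3.67), and Col1a1, the other type 1 collagen chain, was 2.95-fold higher (2.83 to 3.09). Ranges in brackets are exact 95% intervals of the ratio of the libraries. For a gene at 0 in a library, "at least" sets the other count against 3 counts, and the smaller limit of its exact interval follows in brackets. Of 9369 genes tested, 757 were called higher and 798 lower, which is 16.6% of those tested. Each group is 1 library, so these differences have no replicate check, and the exact test on reads compares the libraries and not the conditions. Unchanged genes simulated with an assumed coefficient of variation between preparations of 0.2 gave 275 calls and with 0.4 gave 1857 calls, against 1555 observed. A minimum of 50 counts left 396 higher and 484 lower, a ratio of at least 3 left 443 and 445, and Bonferroni adjustment left 288 and 333. Of 131 called genes taken by the naming rule, 92 were also called with a minimum of 50 counts, 106 with a ratio of at least 3 and 96 with Bonferroni adjustment.

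**Figure D1:**
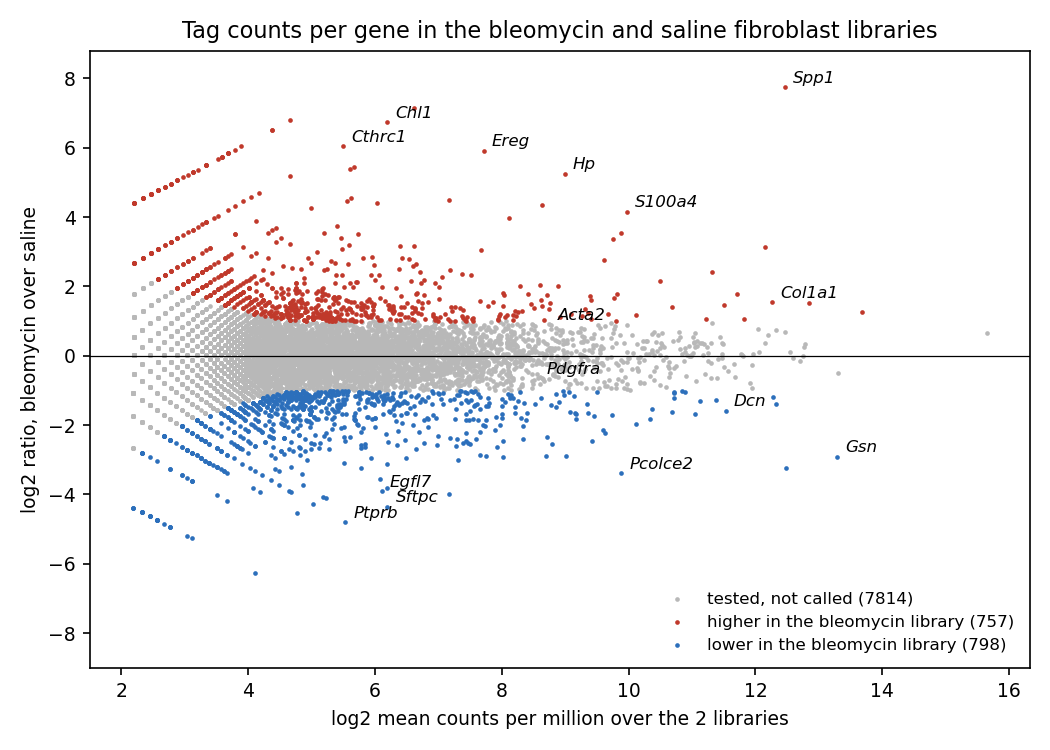
Each point is 1 of the 9369 tested genes, with the log2 mean CPM of the libraries on the x axis and the log2 ratio of bleomycin over saline on the y axis, with 0.5 added to each count. Red points are the 757 genes called higher in the bleomycin library, blue points the 798 called lower and grey points those without a call, and the diagonal streaks at low abundance are genes with 0 or few counts in a library.

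Genes that report on the sort were examined first, whatever their values. Col3a1, the type 3 collagen chain, stood at 4087 and 6186 counts, a ratio of 1.53 (1.47 to 1.59) that stayed under the required 2-fold. The same was so for Acta2, smooth muscle actin, at 328 and 609 counts and a ratio of 1.88 (1.64 to 2.15). Pdgfra, a receptor of lung fibroblasts, had 509 and 323 counts and a ratio of 0.642 (0.556 to 0.739). Ptprc, which encodes the leukocyte surface protein CD45, had 0 counts in the saline and 1 in the bleomycin library, and Epcam, an epithelial adhesion molecule, had 1 and 0, so neither was tested. Pecam1, an adhesion molecule of endothelium, had 53 and 3 counts and was 17.5-fold lower (5.66 to 87.4).

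The 12 largest ratios included genes on the lists of fibrosis-associated and of cell cycle genes. Spp1, the secreted phosphoprotein osteopontin, went from 57 to 12155 counts and was 216-fold higher (166 to 285). Cthrc1, a secreted protein of injured and fibrotic tissue, was 98.1-fold higher (17.2 to 3914). Ereg, the epidermal growth factor receptor ligand epiregulin, was 64.9-fold higher (31.2 to 162), and Hp, the haemoglobin-binding protein haptoglobin, was 38.9-fold higher (26.8 to 58.8). The cell adhesion molecule Chl1 was 159-fold higher (28.1 to 6311), the phospholipid-binding annexin Anxa8 54.6-fold higher (14.8 to 457) and the secreted glycoprotein Lrg1 52.6-fold higher (14.2 to 440.0). Rrm2, a subunit of ribonucleotide reductase, was 54.6-fold higher (9.39 to 2196), and Cdk1, the kinase that drives mitosis, was at least 18.5-fold higher (exact limit 14.6), with 0 counts in the saline library and 55 in the bleomycin library. Chl1, Cthrc1 and Rrm2 had 1 saline count each, and Anxa8 and Lrg1 had 2, so the size and order of these ratios are uncertain. With a prior count of 5, the log2 ratio was 3.31 for Rrm2 and 3.60 for Cdk1. C1qtnf6, a secreted protein related to complement C1q, was 23.2-fold higher (13.3 to 44.1).

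Markers of endothelium and a single marker of alveolar type 2 cells, Sftpc, were among the 12 smallest ratios. Ptprb, a phosphatase of vascular endothelium, was 32.3-fold lower (10.7 to 159), and Cldn5, a tight junction protein of endothelium, was 28.7-fold lower (7.59 to 242). Tie1, an endothelial receptor kinase, was 17.1-fold lower (5.55 to 85.8), Egfl7, a secreted endothelial protein, 15.6-fold lower (7.99 to 34.8), and Cd93, a surface glycoprotein of endothelial and myeloid cells, 18.8-fold lower (7.04 to 70.7). Sftpc, the surfactant protein of alveolar type 2 cells, was 21.8-fold lower (10.3 to 55). The amino acid transporter gene Slc7a10 was 22.4-fold lower (7.35 to 111), the fatty acid transporter gene Cd36 14.8-fold lower (5.5 to 56.2) and Cyp4b1, a cytochrome monooxygenase of lung, 19.3-fold lower (7.24 to 72.5). Tspan7, a tetraspanin, was 14.8-fold lower (7.85 to 31.6), and Mapt, the microtubule-binding protein tau, was 12.3-fold lower (6.67 to 25.2). Pecam1 completed the set.

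Collagen genes were called higher more often than lower. Of 20 tested members of the collagen list, 10 were higher and 2 lower, and 10 and 2 were called when adjusted over the list alone. Their median log2 ratio was 1.09, and 0 of 10000 random lists matched on abundance had a median as high. With a minimum of 50 counts the median was 0.62 over 17 members, and with no minimum 1.58 over 22. Col11a1, a chain of a minor fibrillar collagen, was at least 8.76-fold higher (exact limit 6.63) from 0 to 26 counts, and Col28a1, a beaded-filament type of collagen, was 8.09-fold higher (2.46 to 42). The fallen members were Col13a1, a transmembrane collagen, at 6.05-fold lower (3.6 to 10.8), and Col14a1, a fibril-associated collagen, at 3.61-fold lower (2.82 to 4.66). Enzymes and chaperones that fold, trim and crosslink collagen had 8 of 32 members higher and 2 lower, the counts also found when adjusted over the list alone, with a median log2 ratio of 0.62 and 0 of 10000 random lists as high. Lox, lysyl oxidase, which crosslinks collagen, was 3.03-fold higher (2.23 to 4.18), and P4ha3, a subunit of prolyl hydroxylase, was 3.6-fold higher (2.04 to 6.72). In contrast, Pcolce2, an enhancer of procollagen cleavage, fell from 1895 to 180 counts and was 10.4-fold lower (8.93 to 12.2), and Leprel2, a prolyl hydroxylase of the endoplasmic reticulum, was 5.19-fold lower (1.75 to 20.8).

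Other matrix genes were called in both directions. Among matrix glycoproteins and elastic fibre genes, 11 of 38 were higher and 10 lower (11 and 11 adjusted over the list alone), and the median log2 ratio of 0.16 lay at percentile 89.5 of random lists. Spp1 and Cthrc1 led the higher members, whereas Tgfbi, a secreted integrin-binding protein, was 26.7-fold lower (4.4 to 1093) and Tnxb, a tenascin, was 8.9-fold lower (5.3 to 16). Of 22 proteoglycan and hyaluronan genes, 4 were higher and 4 lower (5 and 4 adjusted over the list alone), with a median of −0.23 at percentile 9.1. Sdc1, a cell surface heparan sulphate proteoglycan, was 22.9-fold higher (10.3 to 63.6), and Gpc4, a glypican, was 5.06-fold higher (2.07 to 14.9). Dcn, decorin, a small proteoglycan that binds collagen, was 2.99-fold lower (2.83 to 3.17), and Ogn, a related small proteoglycan, was 3.57-fold lower (3.27 to 3.92). Basement membrane genes had 3 of 16 higher and 3 lower (3 and 3 adjusted over the list alone), with a median of −0.24 at percentile 15.4. Lama5, a laminin chain, was 2.74-fold higher (1.8 to 4.28), and the type 4 collagen chain Col4a2 was 2.66-fold higher (2.47 to 2.87), while Col4a4 was at least 3.63-fold lower (exact limit 2.48) from 11 counts to 0 and Col4a6 was 2.89-fold lower (1.51 to 5.91). With a minimum of 50 counts the proteoglycan median passed the lower limit of random lists (−0.40), and with no minimum the basement membrane median did (−0.46).

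Most lung fibrosis-associated fibroblast genes were higher, with 21 of 31 members higher and 3 lower (22 and 3 adjusted over the list alone). Its median log2 ratio was 2.02, with 0 of 10000 random lists as high. The list was drawn from general knowledge of fibrotic lung fibroblasts, bleomycin models included, and is not an independent choice. Spp1 had its largest ratio, and the 3 lower members included Lrrc17, a secreted leucine-rich repeat protein, at 3.41-fold lower (2.24 to 5.35), and Sulf2, an extracellular heparan sulphatase, at 2.37-fold lower (1.53 to 3.76). The third, Cd9, a tetraspanin named after its values were seen, was 2.26-fold lower (1.67 to 3.09).

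Growth factor pathways had genes called in both directions. TGF-beta ligands, receptors, regulators and targets had 5 of 30 members higher and 5 lower (5 and 5 adjusted over the list alone), with a median of 0.09 at percentile 73.2. The ligand gene Tgfb1 was 3.9-fold higher (2.69 to 5.8) and Inhba, the activin A subunit, was 6.5-fold higher (3.68 to 12.4). By contrast Acvrl1, a receptor of this family found mainly on endothelium, was 7.25-fold lower (3.08 to 20.8) and Bambi, a decoy receptor, was 4.18-fold lower (3.04 to 5.85). BMP and Wnt pathway genes had 8 of 34 higher and 10 lower (8 and 10 adjusted over the list alone), with a median of 0.04 at percentile 63.4, or −0.0038 with total counts. The BMP antagonist Grem1 was at least 9.44-fold higher (exact limit 7.18) from 0 to 28 counts, and Fst, follistatin, which binds activin, was 16-fold higher (11.4 to 23). The Wnt ligand Wnt2b was at least 3.63-fold lower (exact limit 2.48) from 11 counts to 0, and Wnt5b was 4.38-fold lower (1.89 to 11.8). Among matrix proteases and their inhibitors, 8 of 33 were higher and 6 lower (8 and 6 adjusted over the list alone), with a median of −0.06 at percentile 37.2, or 0.12 with no minimum count and −0.17 with a minimum of 50. Adam12, a membrane metalloprotease, was at least 15.2-fold higher (exact limit 11.8) from 0 to 45 counts and the collagenase Mmp13 at least 6.74-fold higher (exact limit 4.99) from 0 to 20 counts. The membrane-anchored protease inhibitor Reck was 3.46-fold lower (2.08 to 6.01) and Serpinf1, pigment epithelium-derived factor, was 3.2-fold lower (2.63 to 3.91).

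Genes that mark resident lung fibroblasts were called lower more often than higher. Of 30 alveolar fibroblast and lipofibroblast genes, 15 were lower and 2 higher (16 and 2 adjusted over the list alone), with a median log2 ratio of −1.05 and 0 of 10000 random lists as low. Slc7a10 and Tgfbi had the smallest ratios, while Lpl, lipoprotein lipase, was 3.5-fold higher (2.86 to 4.29) and the parathyroid hormone receptor gene Pth1r was 2.29-fold higher (1.31 to 4.16). Of 28 adventitial fibroblast genes, 17 were lower and 0 higher (17 and 0 adjusted over the list alone), with a median of −1.38 and 0 of 10000 random lists as low. Gsn, which encodes the actin-severing protein gelsolin, fell from 19346 to 2548 counts and was 7.51-fold lower (7.2 to 7.83). Dpp4, a membrane peptidase, was at least 4.28-fold lower (exact limit 3.01) from 13 counts to 0, and the alcohol dehydrogenase gene Adh7 was 7.05-fold lower (3.34 to 17.1). Markers of endothelium were lower in the same library, with a median log2 ratio of −3.07 over 14 tested genes.

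Contractile genes were called in both directions. Among contractile and myofibroblast genes, 5 of 29 were higher and 3 lower (5 and 3 adjusted over the list alone), and the median of 0.16 lay at percentile 84.8. The muscle intermediate filament gene Des, desmin, was 3.42-fold higher (2.87 to 4.08) and Tes, a focal adhesion protein, was 4.41-fold higher (2.26 to 9.42). Cnn1, the smooth muscle protein calponin, was 4.2-fold lower (1.37 to 17.2) and Synpo2, an actin-binding protein, was 2.75-fold lower (1.24 to 6.69). Markers of smooth muscle cells had 4 of 10 lower and 1 higher (4 and 1 adjusted over the list alone), with a median of −0.99 at percentile 0.16. Hhip, an inhibitor of hedgehog signalling, was the lowest of them at 5.18-fold lower (3.82 to 7.13). With a minimum of 50 counts that median turned to 0.0098 over 5 members, and with a prior count of 5 it was −0.62. Pericyte markers had 4 of 10 lower and 1 higher (4 and 1 adjusted over the list alone), with a median of −0.65 at percentile 2.02, which moved above percentile 2.5 with no minimum (−0.44) or a minimum of 50 counts (−0.29). Cox4i2, a cytochrome oxidase subunit, was 10.6-fold lower (3.86 to 40.8), Higd1b, a hypoxia-inducible domain protein, 7.25-fold lower (3.08 to 20.8), and the laminin chain gene Lamc3 7.17-fold lower (2.52 to 28.1), whereas Postn, periostin, was 3.03-fold higher (2.59 to 3.55). Endothelial markers, with a median of −3.07, and alveolar type 2 markers, with −1.82, were lower in the same library. General mesenchymal and growth factor receptor genes had 4 of 30 higher and 4 lower (4 and 4 adjusted over the list alone), with a median of −0.01 at percentile 44.7. S100a4, a calcium-binding protein also called fibroblast-specific protein, was 18-fold higher (14.9 to 21.8) and the surface glycoprotein Thy1 was 5.1-fold higher (3.27 to 8.26). The transcription factor gene Twist2 was 2.87-fold lower (1.36 to 6.6) and Eng, endoglin, a coreceptor for TGF-beta, was 2.47-fold lower (1.3 to 4.97).

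Of 28 tested cell cycle genes, 19 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median log2 ratio of 2.33, or 2.27 with genes at 0 set to their bound, and 0 of 10000 random lists as high. It was 1.504 with a prior count of 5 and 1.70 with a minimum of 50 counts, over 11 members. Besides Cdk1 and Rrm2, the cyclin gene Ccna2 was at least 10.8-fold higher (exact limit 8.28) from 0 to 32 counts and Prc1, which organises the mitotic spindle midzone, was at least 5.06-fold higher (exact limit 3.63) from 0 to 15 counts. The median count of these genes was 4 in the saline library and 30 in the bleomycin library, so many of these ratios rest on few tags. Genes of the p53 and DNA damage response had 4 of 27 higher and 4 lower (4 and 4 adjusted over the list alone), with a median of 0.08 at percentile 66.3, or 0.27 with no minimum count. The p53 targets Zmat3 and Eda2r were 6.32-fold higher (2.18 to 25) and 4.05-fold higher (1.47 to 13.8), and the p53 targets Rrm2b and Sesn1 were 4.8-fold lower (2.1 to 12.8) and 3.3-fold lower (1.53 to 7.89).

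Chemokine and cytokine genes had 5 of 27 higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.32 at percentile 96.5, which passed the upper limit with no minimum count (0.45) and turned to −0.03, at percentile 45.5, with a minimum of 50 counts. Il11, a cytokine of the interleukin-6 family, was 8.34-fold higher (4.0 to 20.1) and Csf2, a myeloid growth factor, was 6.57-fold higher (1.49 to 60.0), while Ccl11, the eosinophil chemokine eotaxin, was 2.39-fold lower (1.87 to 3.05). Interferon-induced and antigen presentation genes had 8 of 32 lower and 0 higher (9 and 0 adjusted over the list alone), with a median of −0.78 and 0 of 10000 random lists as low. The major histocompatibility genes H2-Eb1 and H2-K1 were 7.91-fold lower (1.86 to 70.9) and 5.67-fold lower (3.25 to 10.6), Cd74, the invariant chain, was 4.45-fold lower (2.56 to 8.2) and the interferon-induced GTPase gene Igtp was 3.83-fold lower (1.72 to 9.65). Endothelial markers, at a median log2 ratio of −3.07, were lower beside them. Of 18 complement and acute phase genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone), with a median of 0.05 at percentile 59.0, or −0.23 with a minimum of 50 counts and 0.29 with no minimum. Saa3, serum amyloid A, was 6.81-fold higher (5.9 to 7.88), the complement inhibitor gene Cd55 was 3.67-fold lower (2.31 to 6.02) and C1s, a protease of the classical complement pathway, was 2.23-fold lower (1.98 to 2.53). Prostaglandin and eicosanoid genes had 1 of 15 higher and 3 lower (1 and 3 adjusted over the list alone), with a median of −0.18 at percentile 22.9. Ptgs1, a cyclooxygenase, was 2.63-fold higher (1.86 to 3.76). Hpgd, which degrades prostaglandins, was at least 3.96-fold lower (exact limit 2.75) from 12 counts to 0, and the receptor genes Ptgfr and Ptgir were 6.78-fold lower (3.05 to 17.8) and 6.26-fold lower (1.84 to 33).

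Oxidative phosphorylation genes had 2 of 41 higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.30 at percentile 99.0. Both, Uqcrh at 2.22-fold higher (1.77 to 2.8) and Uqcrq at 2.1-fold higher (1.75 to 2.54), encode subunits of respiratory complex III. Glycolysis and hypoxia-responsive genes had 5 of 22 higher and 2 lower (5 and 2 adjusted over the list alone), with a median of 0.33 at percentile 97.4, just under the upper limit that it passed with DESeq2 size factors (0.31), total counts (0.29), no minimum (0.40) and a minimum of 50 (0.40). The hypoxia-responsive gene Ndrg1 was 2.49-fold higher (1.56 to 4.09) and Pkm2, pyruvate kinase, 2.36-fold higher (1.75 to 3.22). Epas1, a hypoxia-inducible transcription factor abundant in endothelium, whose markers had a median of −3.07, was 5.27-fold lower (4.05 to 6.95), and Pfkfb3, a regulator of glycolysis, was 2.1-fold lower (1.44 to 3.1), a call lost with a prior count of 5. Lipid metabolism genes had 6 of 32 lower and 3 higher (6 and 3 adjusted over the list alone), with a median of −0.31 at percentile 2.46, which total counts (−0.35) and no minimum (−0.31) left above percentile 2.5. Besides Cd36 and Lpl, Idi1, an enzyme of isoprenoid synthesis, was 3.67-fold lower (2.31 to 6.02) and the fatty acid elongase gene Elovl6 was 10.1-fold higher (1.44 to 439). Cd36 fell from 60 to 4 counts beside the lower endothelial markers, and which cells its tags came from was not tested.

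Endoplasmic reticulum folding and unfolded protein response genes had 1 of 36 higher and 4 lower (1 and 4 adjusted over the list alone), with a median of −0.13 at percentile 16.0. Ssr4, a subunit of the translocon-associated complex, was 2.59-fold higher (1.91 to 3.54), and the stress response genes Atf3, Ppp1r15a and Atf4 were 3.74-fold lower (2.59 to 5.53), 3.51-fold lower (3.07 to 4.03) and 2.63-fold lower (1.89 to 3.72). Cytosolic ribosomal protein genes had 2 of 56 higher and 2 lower (2 and 2 adjusted over the list alone), with a median of 0.11 at percentile 84.0. Rpl41 was 2.2-fold higher (1.96 to 2.47), Rps10 2.04-fold higher (1.49 to 2.82) and Rps4x 3.24-fold lower (2.35 to 4.52). The Rps10 call was lost with total counts and with a prior count of 5. These genes have many processed pseudogenes that can share tags, so their values are uncertain.

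Antioxidant and xenobiotic metabolism genes had 11 of 34 lower and 3 higher (11 and 4 adjusted over the list alone), with a median of −0.06 at percentile 33.6. Gstm1, a glutathione transferase, was 7.41-fold lower (6.18 to 8.94) and Aox3, an aldehyde oxidase, was 6.59-fold lower (2.78 to 19). The metallothionein gene Mt2 was 2.88-fold higher (2.78 to 2.98) and Prdx5, a peroxiredoxin, was 2.71-fold higher (2.21 to 3.34). Immediate early and dissociation-induced genes, which respond within minutes to stimulation and to tissue digestion, had 7 of 33 lower and 1 higher (7 and 1 adjusted over the list alone), with a median of −0.65 and 0 of 10000 random lists as low. The nuclear receptor gene Nr4a1 was 4.42-fold lower (3.91 to 5.02) and Zfp36, which destabilises messenger RNA, was 3.2-fold lower (2.99 to 3.43), whereas Hsph1, a heat shock protein, was 2.06-fold higher (1.66 to 2.58). The endothelial marker median of −3.07 belongs to the same comparison.

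**Figure D2:**
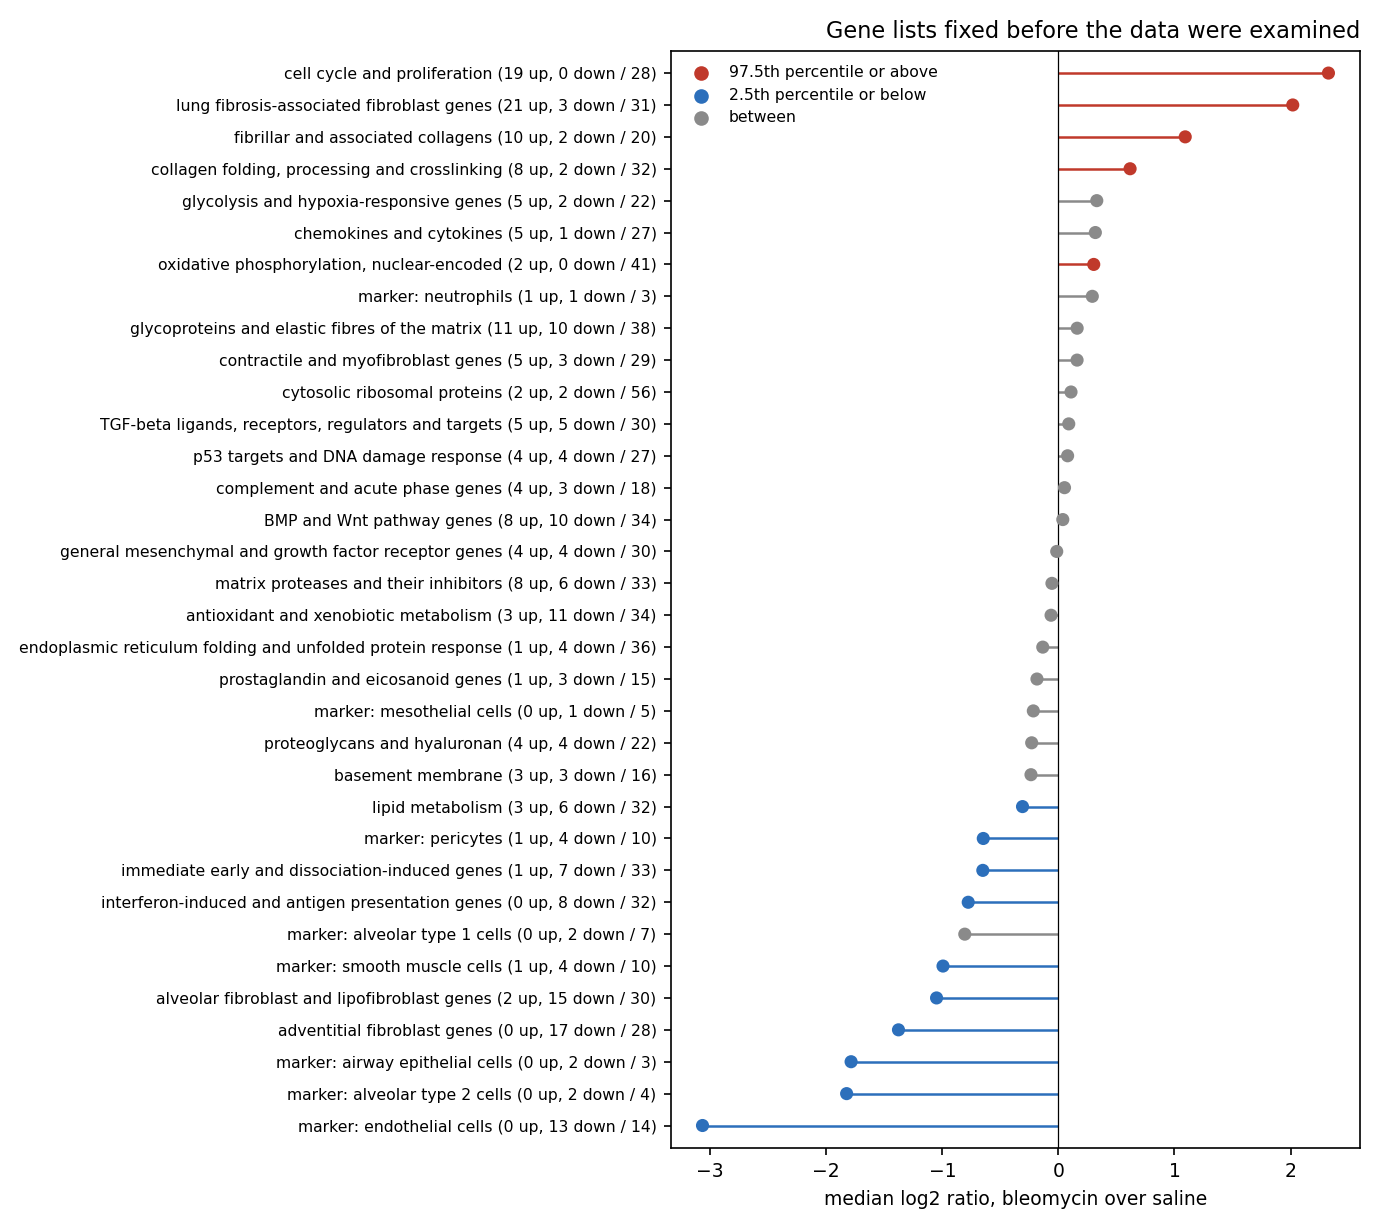
Median log2 ratio of bleomycin over saline of the 34 lists with at least 3 tested members, with the number of members called higher and lower and the number tested in brackets. Colours give the percentile of each median among 10000 random lists matched on abundance; cell cycle genes (2.33) and endothelial markers (−3.07) lie at the ends of the plot.

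Endothelial markers had 13 of 14 lower and 0 higher (13 and 0 adjusted over the list alone), with a median log2 ratio of −3.07 and 0 of 10000 random lists as low. Car4, a carbonic anhydrase of lung capillaries, was at least 12.5-fold lower (exact limit 9.7) from 38 counts to 0. Alveolar type 2 markers had 2 of 4 lower and 0 higher (2 and 1 adjusted over the list alone), with a median of −1.82 at percentile 0.17. With Sftpc stood Lyz1, a lysozyme, at 5.44-fold lower (2.75 to 12). Alveolar type 1 markers had 2 of 7 lower and 0 higher (2 and 0 adjusted over the list alone), with a median of −0.81 at percentile 3.8, or −0.52 with a prior count of 5 and −0.21 over 3 members with a minimum of 50 counts. The tight junction gene Cldn18 was at least 5.93-fold lower (exact limit 4.35) from 18 counts to 0 and the chloride channel gene Clic5 at least 4.28-fold lower (exact limit 3.01) from 13 counts to 0. Airway epithelial markers had 2 of 3 lower and 0 higher (2 and 0 adjusted over the list alone), with a median of −1.79 at percentile 0.41 that moved above percentile 2.5 with no minimum (−1.12). Scgb1a1, the club cell secretory protein, was 3.79-fold lower (1.98 to 7.86) and Tppp3, a tubulin-binding protein, was 3.46-fold lower (2.88 to 4.17). The airway median is the ratio of Tppp3 itself, which had 535 and 153 counts. Scgb1a1 had 46 and 12 counts and Epcam, also on the list, 1 and 0. That median therefore does not show that airway cell RNA as a whole was lower.

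Few blood cell markers had enough counts to be tested. Of 21 macrophage and monocyte markers matched in the table, only Lpl reached the minimum for testing, and it was higher (1 and 0 adjusted over the list alone). Neutrophil markers had 1 of 3 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.29 at percentile 72.5, or 1.23 over 8 members at percentile 96.9 with no minimum count. Mmp8, neutrophil collagenase, was 32.4-fold higher (5.41 to 1318), and G0s2, an inhibitor of lipolysis, was 7.4-fold lower (5.53 to 10.1). Mmp8 is also on the list of matrix proteases and G0s2 on that of alveolar fibroblast and lipofibroblast genes. Of the lymphocyte markers only Igj, the immunoglobulin joining chain, was tested, at 23 and 19 counts without a call (0 and 0 adjusted over the list alone). Hba-a1, a haemoglobin chain that shares sequence with its neighbour, was 4.1-fold lower (1.76 to 11.1), the 1 lower of 2 tested markers of red cells and platelets (0 higher and 1 lower adjusted over the list alone). Kit, a receptor of mast cells, was 8.4-fold lower (2.0 to 75) as the only tested mast cell marker (0 higher and 1 lower adjusted over the list alone). It had 17 and 2 counts and was the only 1 of 6 matched markers with enough counts, so it does not show fewer mast cells. Which cells its tags came from was not tested. S100b, a calcium-binding protein of Schwann cells, was 4.55-fold higher (1.5 to 18.5), the 1 higher of 2 tested nerve markers (1 and 0 adjusted over the list alone). Mesothelial markers had 1 of 5 lower and 0 higher (1 and 0 adjusted over the list alone), with a median of −0.22 at percentile 35.0, and Bcam, a laminin receptor, was 4.2-fold lower (1.37 to 17.2). Neither of 2 tested lymphatic markers was called (0 and 0 adjusted over the list alone), and Pdpn, podoplanin, had 84 and 95 counts.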

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

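Leaving out predicted transcripts was chosen after seeing the data; the other alternatives were planned. Of 22 alternative counts of called genes, 16 stayed within 1.5 times the count given and 6 did not: a minimum of 50 counts gave 396 higher and 484 lower, a ratio of at least 3 gave 443 and 445, and Bonferroni adjustment gave 288 and 333, each by its own stricter construction or fewer genes tested. Without predicted transcripts the counts were 736 and 768. Higher genes made up 48.7% of calls, and 42.1% with total counts, the lowest share of any alternative. Of 1555 calls, 1482 were also made with DESeq2 size factors, 1473 with total counts, 1551 with totals without the 20 most abundant genes, 1504 with Fisher's exact test, 1529 after thinning, 1406 with a prior count of 5, 888 with a ratio of at least 3, 879 with a minimum of 50 counts and 621 with Bonferroni adjustment.

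Of 201 alternative list medians, 188 kept their side of the percentile limits. Of these, 4 changed sign while inside the limits: BMP and Wnt genes with total counts (−0.0038), matrix proteases with no minimum (0.12), and chemokines (−0.03) and complement genes (−0.23) with a minimum of 50 counts. Of medians that stayed past a limit, 3 moved by over 1.5 times: collagens with a minimum of 50 counts (0.62), and cell cycle genes (1.504) and smooth muscle markers (−0.62) with a prior count of 5. Of medians that stayed inside the limits, 25 over 11 lists moved by over 1.5 times or changed sign, among them neutrophil markers with no minimum (1.23 over 8 members) and alveolar type 1 markers with a minimum of 50 counts (−0.21 over 3). Those that moved to or past a limit were proteoglycans with a minimum of 50 counts (−0.40), basement membrane with no minimum (−0.46), chemokines with no minimum (0.45) and glycolysis with DESeq2 size factors (0.31), total counts (0.29), no minimum (0.40) and a minimum of 50 (0.40). Those that moved back inside were lipid metabolism with total counts (−0.35) and no minimum (−0.31), pericytes with no minimum (−0.44) and a minimum of 50 (−0.29), and airway epithelium with no minimum (−1.12). The smooth muscle median turned to 0.0098 with a minimum of 50 counts, which leaves 5 members. Apart from such changes of members tested, the cause was not tested. For 138 genes taken by the naming rule, 3 other scalings and a prior count of 5 gave 552 ratios, of which 549 kept their direction and call; Pfkfb3 with a prior count of 5 (−0.98) and Rps10 with total counts (0.98) and with a prior count of 5 (0.97) kept their direction and fell under the 2-fold limit. Of the 131 called among them, counted after seeing the data, 131 were also called with Fisher's exact test and after thinning, 106 with a ratio of at least 3, 96 with Bonferroni adjustment and 92 with a minimum of 50 counts.

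Keeping the most abundant of entries that share a symbol changed nothing because no symbol was shared, and the alternatives planned for normalized values did not apply to counts. No paired analysis was possible because each group has 1 library, and neither leaving out a replicate nor other splits of the samples could be run. Depth and the required ratio of at least 2 both limit the calls at small changes: simulated 2.5-fold changes were recovered for 42.0% of genes.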

Other observations

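All tests of explanations in this part were chosen after the results were seen, except the percentile of the retinoid genes, whose limits were set before the values of that set were seen.

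Several genes outside the naming rule were chosen after their values were seen. Fn1, fibronectin, had 1018 and 8890 counts in saline and bleomycin and was 8.83-fold higher (8.28 to 9.43). Timp1, an inhibitor of metalloproteases, was 11.7-fold higher (9.95 to 13.8). Areg, amphiregulin, an epidermal growth factor receptor ligand like Ereg, was 22.2-fold higher (7.29 to 111). At the other end, Inmt, a methyltransferase abundant in lung fibroblasts, had 11323 and 1197 counts and was 9.35-fold lower (8.81 to 9.94).

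Several genes that bind, store or oxidise retinoids, also chosen after their values were seen, were lower in the bleomycin library. Rbp4, which binds retinol, was 8.04-fold lower (5.73 to 11.6), Lrat, which esterifies retinol for storage, was 6.16-fold lower (4.52 to 8.58) and Aldh1a1, a retinal dehydrogenase, was 5.41-fold lower (3.65 to 8.27). In contrast Cyp26b1, which degrades retinoic acid, was 6.9-fold higher (3.64 to 14.4). Of 10 such genes, 6 were lower and 1 higher, and those without a call included the retinal dehydrogenases Aldh1a2, at 48 and 75 counts, and Aldh1a3, at 11 and 15 counts. A hypothesis that retinoid genes shift together was then tested on 28 further genes whose values had not been seen. Of these, 9 could be tested, with 1 lower, 0 higher and a median log2 ratio of 0.42, at percentile 92.0 of random lists. That result goes against a general shift of retinoid genes, and the lower values stay a description of the genes first noticed.

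Spp1 reached 12155 counts in the bleomycin library, and macrophages, which express it strongly in injured lung, are a candidate source. The 20 macrophage and monocyte markers other than Lpl had 11 counts together in the saline library and 30 in the bleomycin library. Those 30 are 0.247% of the Spp1 count in the bleomycin library, where the highest single marker had 8. Lyz2, the lysozyme of these cells, had 4 counts in saline and 1 in bleomycin. Of 21 macrophage markers matched, 6 are also on another list, and a lineage sort normally removes such cells, though the labels do not name its markers. These values argue against macrophages or their RNA as the source. The totals differ 1.02-fold and ratios were scaled to library size. After the deeper library was thinned, 1529 of 1555 calls remained, with all 131 called genes of the naming rule, Spp1 included. These values argue against the depth of the deposited counts as the source, while scaling before deposit stays open. Treatment, which fibroblasts the sort collected and preparation of the library stay open as explanations that 1 library per group cannot separate.

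Endothelial markers were lower for 13 of 14 tested, and endothelial cells carried over into the saline library, and less into the bleomycin library, are a candidate source. The 13 lower markers had 578 counts in saline and 58 in bleomycin, 9.85-fold lower when pooled, and all 14 had 660 and 113 counts, 5.78-fold lower. Their ratios spread more than counting error allows (permutation p = 0.00021, 100000 draws), with Ednrb and Eng, which other lung cells also express, lowered by less than the pooled ratio. The other 11 were 13.9-fold lower when pooled, with a spread that counting error could give (permutation p = 0.449), but they were what remained after the deviating genes were removed. Neither test decides, because both cover counting error and not the differences between preparations of cells, which 1 library per group cannot measure. A first look had counted markers whose interval left out the pooled ratio, which was 2, and was replaced after its result was seen. Carried-over cells and a change within the sorted cells therefore cannot be told apart. Plvap, the other tested marker, had 82 and 55 counts without a call. Of the 16 markers matched, 1 is also on another list, and the labels do not say whether the lineage sort covered endothelium. The totals differ 1.02-fold and ratios were scaled to library size, which argues against the depth of the deposited counts here too. Scaling before deposit stays open.

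The list of immediate early and dissociation-induced genes had a median log2 ratio of −0.65, and a weaker response to tissue dissociation as a whole is a candidate explanation. The 7 heat shock members of the list, which such a response would also lower, had a median log2 ratio of −0.09 (SD 0.488) with 6 of them below a ratio of 1, against −0.76 for the 26 other members with 22 below 1. The difference of 0.669 was larger than that SD, which is a spread over 7 genes and not the error of a difference of medians. Heat shock genes are also among those with uncertain tags. The comparison therefore does not decide whether the response was weakened by the same amount over the whole list. A weaker response, even or smaller for the heat shock genes, a difference in digestion that touches only the other members, and an effect of bleomycin stay open.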
